A study of Drosophila melanogaster with 40 samples.

How the data were processed

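The assay was chromatin immunoprecipitation followed by sequencing (ChIP-seq) of Capicua (Cic), an HMG-box transcriptional repressor, in early Drosophila embryos of nuclear cycle 14. Cic carried super-folder GFP at its own locus and was pulled down with an antibody against GFP. The labels list 40 libraries, 20 of immunoprecipitated DNA and 20 of 1% input. Each group had 3 biological replicates of each kind, except the embryos given 1 min of light, which had 2.

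The deposited files start after alignment. BWA 0.7.17-r1188, Trim Galore, SAMtools, MACS2, ChIPseeker and the genome build dm6 are named in the submitters' processing notes. Peaks were called with MACS 2.1.2 on the pooled wild type ChIP libraries against the pooled libraries of untagged embryos, per the file headers. The header gives 6994179 wild type tags and 5712080 untagged tags, a tag size of 74 bp, an extension of 145 bp without a fitted fragment model, all duplicates kept and a q threshold of 0.01. Fold enrichment, the ratio of the wild type pileup to the local untagged level, was deposited for each peak. The pileup at the summit, a read coverage signal after extension, was deposited by the authors for each call. Significance was deposited as -log10 p and -log10 q values, per the file headers. A score of 10 times -log10 q was deposited beside them in the final list. That list had 103 peaks, annotated to genes by the authors, and the filter behind it is not given in the sources used here.

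The authors deposited 1 matrix of z-scores per condition for wild type, no light, 1, 5 and 30 min of light and constitutively active Torso. Each deposited score is a z-score of depth-scaled read counts in a 10 bp window, normalised on reads in noise peaks, per the contents sheet of the workbook. This was read as 0 at the mean and 1 at the SD of the noise peaks of that condition. The sheet puts peaks in rows and windows in columns, and the matrices hold them the other way round. Each matrix held 201 windows over 2 kb for 103 peaks, and replicates were already combined. Hence no test across samples was possible, no p-value is given for any change in signal, and the spread between replicates is unknown. Input libraries and a signal matrix of the untagged embryos were not used here.

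Columns carried no names, so their order was checked. Where windows of neighbouring peaks overlap, the same coverage should appear in both columns. Taking columns in the order of the peak list, 36 of 42 such pairs of windows in 1 condition matched exactly over their shared part, against 0 of 200 unrelated pairs. The shifts differed between conditions, and 87 to 103 windows per condition had their highest point within 200 bp at the centre. Windows were therefore centred on the highest point of each condition and not on a common position, which raises weak signals. Flanks of the 30 min windows reached 1.84 times the noise level when centred in the same way within 200 bp, which can make the folds at 30 min too small. Values of a peak in several conditions can also come from neighbouring places and not from 1 position.

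All z-scores of a matrix lay on whole steps of 1 size above the lowest value. The steps were read as read bases per window and the lowest value as no coverage. In the wild type matrix 197 windows held the lowest value, 4 lay 1 step above it and 317 lay 10 steps above it. On that reading the mean coverage of the noise peaks was 3.93 reads in wild type, 4.33 in no light, 2.83 in 1 min, 3.90 in 5 min, 3.47 in 30 min and 4.30 in active Torso. Coverage over noise, the recovered coverage divided by that mean, has a true zero and was used for folds.

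The value of a peak was the mean z-score within 250 bp of the window centre, and conditions were compared by differences of z-scores because these can be negative. Medians over peaks have 95% order-statistic intervals, which describe the spread over peaks, not over embryos. Folds have 95% exact conditional intervals on read equivalents, that is read bases divided by 74. The median peak had 168 read equivalents in wild type, 221 in no light, 193 in 1 min, 97.2 in 5 min, 60.7 in 30 min and 92.6 in active Torso. These intervals cover counting error only. A peak is called lower or higher beyond counting error where its interval excludes 1. With no change and counting error alone, about 5% of peaks would be so called. Scatter between libraries can raise this share by an unknown amount. Without any light, no light against wild type had 48 peaks called higher and 3 lower.

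The choices of window, comparisons, alternatives, gene lists and the rule for named genes were made before the data were examined. The rule named every member of the fixed lists that the authors annotated to a final peak and the 10 highest wild type peaks. For each comparison it added the 5 largest falls and the 5 smallest falls or largest rises among peaks at or above the median reference signal. Peaks of a gene with several are numbered by deposited score. The 10 lists covered known Cic targets, the receptor tyrosine kinase and ERK pathway, gap, terminal and head genes, pair-rule and segment polarity genes, dorsoventral genes, Hox genes, neurogenic genes, cell cycle genes, genes of zygotic activation and cellularization, and housekeeping genes. Of their 180 entries, 179 matched the Release 6 gene table, as did 87 of 88 gene symbols of the peak list. Membership was tested with a one-sided Fisher's exact test against 13946 protein-coding genes, with Benjamini-Hochberg adjustment over the 10 lists. The median change of a list was placed among 10000 random lists of equal size matched on reference signal in 5 classes. Peaks of 1 gene were counted singly there, so percentiles describe these matrices only.

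Alternatives were windows of 100 and 500 bp on each side, subtraction of the flank, scaling to an equal flank, the maximum in place of the mean, a log2 scale with 1 added, peaks at or above the median reference signal only, stricter MACS2 thresholds and other distances to genes. The log2 ratio without 1 added, 1000 bp on each side, removal of 14 peaks with overlapping windows, gene bodies within 10000 bp with 1000 random placements of the peaks, and windows aligned to those of the reference by profile shape within 400 bp were added after seeing the data. The distances between overlapping windows check this alignment, and 30 of 33 changes of distance were met within 50 bp, or 21 of 22 where both profiles had a correlation of at least 0.7. The design had foreseen a motif search and random placement around start sites, which were not run because no genome sequence or strand was at hand. The list function was tested on random numbers, with values unrelated to reference signal. There 9% of random lists lay under percentile 5 or over 95. The comparison functions were tested on simulated reads made from the no light matrix, with counting error only. All 20 peaks set to 0.25 of their excess signal and all 20 set to 0.5 were called lower beyond counting error, as were 3 of 63 peaks left as they were. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.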

Results

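Binding of Cic was profiled in nuclear cycle 14 embryos of 7 groups. For all groups the labels give a collection of 3 to 4 h and 15 min of fixation. In OptoSOS embryos, blue light recruits a fragment of the Ras activator SOS to the membrane and so switches on Ras and ERK, the kinase that acts on Cic. These embryos received no light or 1, 5 or 30 min of light. Wild type embryos carried tagged Cic without the optogenetic parts, and embryos with the gain-of-function receptor allele TorD4021 carried constant ERK activity from Torso. Untagged OreR embryos showed what the GFP antibody takes down by itself. Sequencing depth was stated only for the pooled peak calls, which used 6994179 wild type and 5712080 untagged tags. All signal values below come from 1 combined matrix per condition and have no replicate error. They cover only peaks called in wild type, so sites bound only in another condition cannot appear. Counts of lower and higher peaks therefore describe this set alone.

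The first question was where tagged Cic binds above the untagged background. The highest of all calls, with 29.2-fold at Dsor1, which encodes the ERK kinase MEK, was not in the final list and is taken up at the end. The highest fold enrichment of the final list, 26.2, belonged to a peak at the promoter of tll, a nuclear receptor gene of the terminal system (chromosome 3R, 30851662 to 30852585, dm6). Next came Doc2, a T-box gene of the dorsal ectoderm, with 24.95 at a distal intergenic peak (3L, 9028911 to 9029715), and hkb, a zinc-finger gene of the terminal system, with 24.7 at a distal intergenic peak (3R, 4348112 to 4348940). The promoter peak of pnt, which encodes an ETS activator downstream of ERK, had 24.3 (3R, 23314231 to 23314688), and that of wntD, a Wnt family gene, had 22.1 (3R, 13293257 to 13293787). MACS2 made 468 calls, of which 360 had a -log10 q of at least 5 and 341 a fold enrichment of at least 3. Every peak of the final list was among these calls at the same position. Fold enrichment in the final list ran from 5.02 to 26.2 with a median of 7.19, and width from 165 to 1164 bp with a median of 381 bp.

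By the authors' annotation 41 peaks were intronic, 27 lay in promoters, 14 were distal intergenic, 4 lay downstream of a gene, 2 in exons and 1 in a 5′ UTR, and 14 had no class. Some peaks without a class, such as srp peak 1 and pros, had a start-site distance of 0 bp, so the promoter count may be too low. The deposited distance to the nearest transcription start site was at most 1000 bp for 39 peaks and at most 3000 bp for 67. Chromosome arm 3R held 34 peaks, 3L 25, 2L 17, 2R 14 and X 13. Of 88 named genes, 11 had more than 1 peak.

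Genes of several patterning systems were found beside Cic peaks more often than all protein-coding genes would give. Among dorsoventral genes 11 of 29 were annotated to a peak, where 0.181 was expected (odds ratio 111, one-sided Fisher's exact test, adjusted p = 9.14e-17). They were Doc2, Doc3, brk, dpp, ind, pnr, sna, ths, tld, zen and zen2, which include the BMP ligand dpp, the repressor gene brk and the mesoderm gene sna. Of the known Cic targets, 5 of 10 had a peak, namely aos, hkb, ind, pnt and tll (odds ratio 169, one-sided Fisher's exact test, adjusted p = 6.89e-09). The receptor tyrosine kinase and ERK pathway had 7 of 31 genes, namely Egfr, Mkp3, aos, cic itself, pnt, sty and ths (odds ratio 50.4, one-sided Fisher's exact test, adjusted p = 3.35e-09). Of the gap, terminal and head genes 4 of 20 had a peak, namely fkh, hkb, pdm2 and tll (odds ratio 41.7, one-sided Fisher's exact test, adjusted p = 1.59e-05). With gene bodies within 10000 bp of a summit in place of the annotated gene, the odds ratios of these lists fell to 51.1, 60.7, 17.8 and 26.1, and none of 1000 random placements of the peaks held as many of their genes. The lists share genes, and known Cic targets were listed from earlier work on Cic. Neighbouring genes such as zen and zen2 were counted singly. The backgrounds took all protein-coding genes or all positions alike. A preference beyond regulatory DNA active in these embryos was therefore not tested.

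The other lists did not pass the same one-sided Fisher's exact test. The pair-rule and segment polarity genes had prd alone (1 of 18, odds ratio 9.47, one-sided Fisher's exact test, adjusted p = 0.152), the Hox genes abd-A alone (1 of 8, odds ratio 23.01, adjusted p = 0.0913) and the neurogenic genes Tom alone (1 of 22, odds ratio 7.66, adjusted p = 0.161). The zygotic activation and cellularization genes had sisA alone (1 of 9, odds ratio 20.1, one-sided Fisher's exact test, adjusted p = 0.0913). No cell cycle gene of 18 and no housekeeping gene of 14 had a peak.

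Central Cic signal was high in wild type, no light and 1 min embryos and low in the other conditions. The median z-score over peaks was 7.29 in wild type (95% interval over peaks 6.52 to 8.91), 8.69 in no light (7.51 to 10.8) and 9.85 after 1 min (8.25 to 11.9). It was 3.47 after 5 min (3.07 to 3.97), 1.93 after 30 min (1.57 to 2.44) and 2.83 with active Torso (2.14 to 3.40). The flanks of the same windows had medians of 0.944, 1.12, 1.29, 0.591, 0.589 and 0.584 in the same order of conditions. Each flank was centred on its highest point over a shorter stretch than the peak windows, which can make these values too low.

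**Figure D1:**
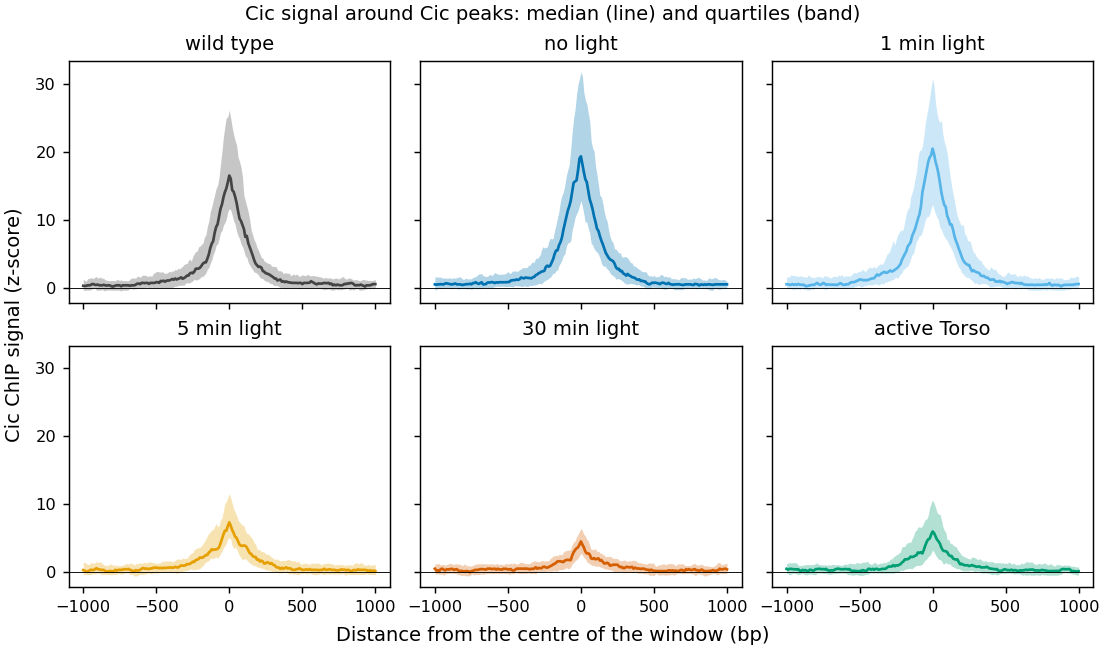
Median z-score of Cic ChIP signal over the final peaks (line) with quartiles (band) against distance from the window centre in bp, with 1 panel per condition. The median at the centre was 16.5 in wild type, 19.3 in no light, 20.5 after 1 min, 7.36 after 5 min, 4.55 after 30 min and 6.01 with active Torso.

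**Figure D2:**
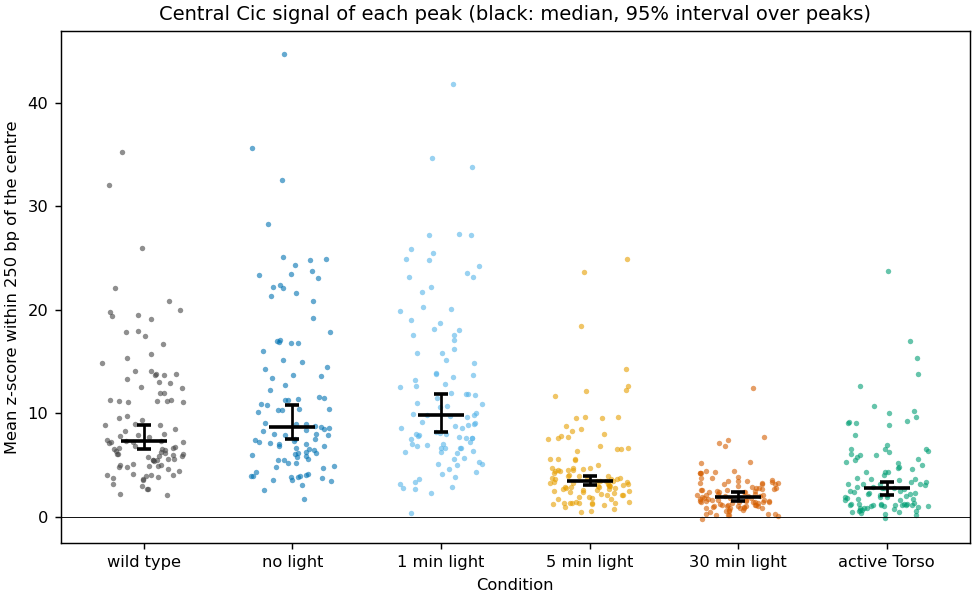
Mean z-score within 250 bp of the centre for each final peak (points) by condition, with the median and its 95% interval over peaks in black. The medians fall from 9.85 after 1 min to 3.47 after 5 min and 1.93 after 30 min of light.

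No light was compared with wild type to set the optogenetic line beside embryos without it. A difference between lines and one between libraries cannot be separated here. Cic signal was slightly higher in the dark OptoSOS embryos at most peaks. The z-score was higher at 84 peaks and lower at 19, with a median difference of 1.30 (95% interval 0.778 to 2.40). Coverage over noise was 1.19 times that of wild type at the median peak, higher beyond counting error at 48 peaks and lower at 3, namely CG42807, Shroom and CG13716. The 3 were singled out after their values were seen. The highest wild type peak, tll peak 1, had nearly equal z-scores, 35.3 in wild type and 35.6 in no light, and a ratio of 1.04 (95% counting interval 0.939 to 1.15).

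Among dorsoventral genes 11 of 12 peaks were higher and 10 were so beyond counting error. The peak of tld, a metalloprotease gene of the BMP system, had a ratio of 1.51 (1.28 to 1.77), and that of zen2, a homeobox gene beside zen, had 1.498 (1.28 to 1.77). Their median z difference of 3.84 lay at percentile 98.6 of matched random lists, and their median ratio of 1.27 at percentile 80.4. The gap, terminal and head genes rose less than matched lists, with a z difference of 2.80 (percentile 2.01) and a ratio of 1.18 (percentile 2.71). Of 11 peaks of known Cic targets 9 were higher and 6 were so beyond counting error, with ratios of 1.49 (1.31 to 1.69) at pnt peak 1 and 1.42 (1.28 to 1.57) at hkb peak 1. In the receptor tyrosine kinase list 10 of 11 peaks were higher, 5 of them beyond counting error. The negative feedback gene sty had the highest ratio of all peaks, 1.74. CG42807 had the lowest, 0.525. This range was used as a measure of how far peaks differ between conditions without light.

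The comparison of 1 min of light with no light asked whether binding changes within the first minute. Fixation lasted 15 min, longer than the pulses of 1 and 5 min, so timing may be coarser than the pulse lengths. No general loss of Cic was seen. The z-score was higher at 70 peaks and lower at 33, with a median difference of 0.639 (0.355 to 0.926). At the median peak coverage over noise was 1.26 times that of no light, and it was higher at 97 peaks and lower at 6. Only Cyt-b5-r, singled out after its value was seen, was lower beyond counting error, with z-scores of 0.419 after 1 min and 2.57 in no light, whereas 65 peaks were higher beyond counting error. By z-score tll peak 1 (34.6 and 35.6), hkb peak 1 (41.8 and 44.7) and pnt peak 1 (27.3 and 28.3) were a little lower after 1 min, whereas their coverage over noise was 1.19, 1.15 and 1.18 times that of no light.

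The largest falls in z-score among strong peaks were at zen, tld, hkb peak 1, Egfr and CG16813. At zen, a homeobox gene of the amnioserosa, the z-score was 20.0 after 1 min and 24.8 in no light, with a ratio of coverage over noise of 0.992 (0.869 to 1.13). Rises were largest at pnt peak 2, Rpn12R peak 1, fend peak 1, CG15480 and CG17300, where pnt peak 2 went from 21.3 to 27.2. The peaks of known Cic targets, the receptor tyrosine kinase list, the gap list and the dorsoventral list had median z differences of 0.355, 0.240, -0.672 and 0.758. These lay at percentiles 28.7, 15.0, 16.1 and 54.7 of matched random lists. Taking the maximum of the window in place of the mean turned the median difference negative, so the direction at 1 min depends on the measure. The 1 min matrix combined 2 libraries and had the lowest noise coverage.

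After 5 min of light Cic signal was lower than in no light across nearly all of the peaks called in wild type. The z-score was lower at 100 peaks and higher at 3, with a median difference of -4.90 (-6.35 to -4.35). Coverage over noise was 2.02-fold lower at the median peak (95% interval over peaks 1.86 to 2.24), lower beyond counting error at 96 peaks, and below the lowest ratio of no light to wild type at 60. The terminal gene tll lost most, with 5.22-fold lower coverage at its promoter peak (4.37 to 6.31) and z-scores of 35.6 before and 5.61 after. By contrast pnt peak 1 kept most of its signal, at 28.3 before and 23.6 after and 1.16-fold lower coverage (1.03 to 1.31). Windows were centred anew in each condition. Aligned by profile shape, that of pnt peak 1 lay 30 bp from its no light position (1.17-fold lower, 1.04 to 1.31) and that of tll peak 1 220 bp away (5.07-fold lower, 4.26 to 6.12).

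All 7 peaks of gap, terminal and head genes were lower beyond counting error. Their median z-score went from 23.5 to 5.61, and the median difference of -15.9 lay at percentile 0.755 of random lists matched on no light signal, whose median was -12.8. Besides tll, the forkhead gene fkh was 2.75-fold lower (2.32 to 3.28), hkb peak 1 2.28-fold (2.03 to 2.57) and the POU gene pdm2 3.24-fold (2.32 to 4.58). All 11 peaks of known Cic targets were lower, with a median of 2.14-fold and no distance from matched lists (percentile 66.2 of the z difference). There the neuroectoderm gene ind was 2.96-fold lower (2.39 to 3.71) and aos, which encodes a secreted inhibitor of EGFR signalling, 1.75-fold at peak 1 (1.35 to 2.31).

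All 11 peaks of the receptor tyrosine kinase list and all 12 of the dorsoventral list were lower beyond counting error too. Fold differences within them were uneven. Egfr, the receptor gene, was 3.41-fold lower (2.75 to 4.27) and the ERK phosphatase gene Mkp3 3.33-fold (2.60 to 4.28). The FGF ligand gene ths was 2.91-fold lower (2.40 to 3.54) and tld 3.06-fold (2.49 to 3.78), whereas sna was 1.32-fold lower (1.12 to 1.55) and Doc3 1.46-fold (1.19 to 1.83). Outside these lists hbn, a homeobox gene of the head, was 4.67-fold lower (3.49 to 6.39) and Rpn12R peak 2 4.52-fold (3.64 to 5.61). Both Rpn12R peaks lie in the same intron as the peak of the known Cic target ind. On 3L, Rpn12R peak 2 spans 15040299 to 15041028 and the ind peak 15045121 to 15045495. Which gene the Rpn12R peaks serve was not tested. The peak of CG12986 was 1.27-fold lower (1.13 to 1.42). The only peak higher beyond counting error was betaTub60D, a beta tubulin gene, a weak peak singled out after its value was seen (ratio 1.34, 1.01 to 1.77).

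After 30 min of light little Cic signal was left. The z-score was lower than in no light at all peaks but 2, Cyt-b5-r and a peak without a gene symbol, with a median difference of -6.90 (-8.20 to -5.98). Coverage over noise was 3.11-fold lower at the median peak (2.81 to 3.37), lower beyond counting error at 98 peaks and higher at none, and beyond the no light to wild type range at 83. The largest falls in z-score were at the highest peaks, while the largest fold was at Rpn12R peak 2 (9.44, 6.94 to 13.2), in the same intron as the ind peak. At tll peak 1 coverage was 9.21-fold lower (7.19 to 11.9) and the z-score 2.45, at hkb peak 1 7.59-fold lower (6.20 to 9.33) and 4.34, and at pnt peak 1 7.38-fold lower (5.75 to 9.53) and 2.45. By shape the 30 min window of hkb peak 1 lay 300 bp away and that of tll peak 1 could not be placed, whereas pnt peak 1 lay within 10 bp.

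Known Cic targets stood out by fold. All 11 peaks were lower beyond counting error, and their median of 5.56-fold compared with 3.74-fold in matched random lists (percentile 2.28 of the ratio). In this list aos peak 1 reached a z-score of 0.220 and was 4.79-fold lower (3.20 to 7.44), and ind was 5.56-fold lower (4.12 to 7.54). The 7 peaks of gap, terminal and head genes had a median of 7.20-fold, with 7.20-fold at fkh (5.50 to 9.51) and 4.74-fold at pdm2 (3.15 to 7.31), against 4.53-fold in matched lists (percentile 1.715). Since 5 of these 7 peaks, those of hkb and tll, are also peaks of known targets, the results of these lists are not separate. Tested on the z difference, known targets lay at percentile 19.5 and the gap list at 0.870.

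The 12 dorsoventral peaks were lower by a median of 3.57-fold, near the 3.66-fold of matched lists (percentile 56.96). Their median z difference of -13.5 was larger than the -10.7 of matched lists (percentile 1.275). They ranged from 6.53-fold at zen2 (4.83 to 8.96) and 5.02-fold at zen (4.02 to 6.32) to 1.79-fold at sna (1.48 to 2.15). The 11 peaks of the receptor tyrosine kinase list had a median of 4.18-fold, with 6.22-fold at Egfr (4.67 to 8.51), 5.08-fold at sty (3.32 to 7.96) and 1.64-fold at cic peak 2 (1.25 to 2.20). Single members of the smaller lists were lower as well, by 3.37-fold at sisA (2.48 to 4.59), 2.85-fold at Tom (2.20 to 3.72), 2.51-fold at abd-A (1.97 to 3.20) and 3.21-fold at prd peak 1 (2.39 to 4.44). CG12986, which has a promoter peak on X (17819364 to 17820471), had the highest z-score left, 12.4, followed among named peaks by sna with 7.73 and CG15480 with 7.39. The untagged MACS2 level at these summits was 2.32, 1.88 and 3.04 times the lowest one, against a median of 1.24 over peaks. Material taken down without tagged Cic may thus be part of what is left there. Doc2 kept a z-score of 6.88 at an untagged level of 1.01.

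Over the series of light durations the fall lay mainly between 1 and 5 min and went on to 30 min. The z-score was lower at 100 peaks from 1 to 5 min and at 93 from 5 to 30 min, and 91 peaks fell at both steps, where these 2 counts alone would give 90.3. Coverage over noise was 2.61-fold lower at 5 min than at 1 min and 1.47-fold lower at 30 min than at 5 min. The last step was beyond counting error at 52 peaks and opposite at none. At the median peak 78.6% of the 30 min fall in z-score had been reached at 5 min (quartiles 66.2% and 88.8%). In this paragraph, shares and folds of single peaks are limited to those whose windows of 5 and 30 min both matched no light. Both had a correlation of at least 0.7 with the no light profile and lay within 250 bp of it. This limit was set after the values were seen and can leave out peaks with little signal left. It was not applied to folds given elsewhere. The share was then 90.7% at ths, 56.6% at srp peak 1, 38.01% at CG12986 and 17.99% at pnt peak 1. From 5 to 30 min pnt peak 1 was 6.34-fold lower (4.92 to 8.22), srp peak 1 3.44-fold (2.65 to 4.55) and ths 1.19-fold (0.922 to 1.56). No such values are given for tll peak 1, hkb peak 1 and pnt peak 2, whose windows moved farther or could not be placed, nor for Egfr and zen2, whose 30 min profiles matched poorly. A fall at every step from no light on was seen at 25 peaks by z-score, where the counts of the single steps alone would give 28.9, and at 3 by coverage over noise. The joint counts thus add nothing to the counts of the steps.

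**Figure D3:**
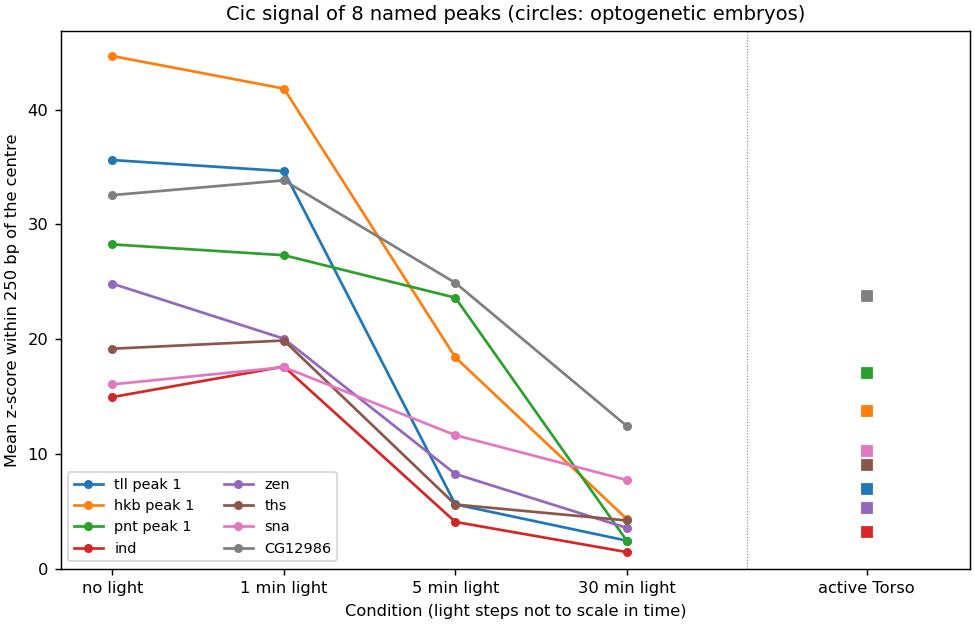
Mean z-score within 250 bp of the centre for 8 named peaks, as circles joined by lines in OptoSOS embryos without light and after 1, 5 and 30 min of light, and as squares with active Torso, in windows centred anew in each condition. At 5 min pnt peak 1 is at 23.6 and tll peak 1 at 5.61, and at 30 min both are at 2.45.

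**Figure D4:**
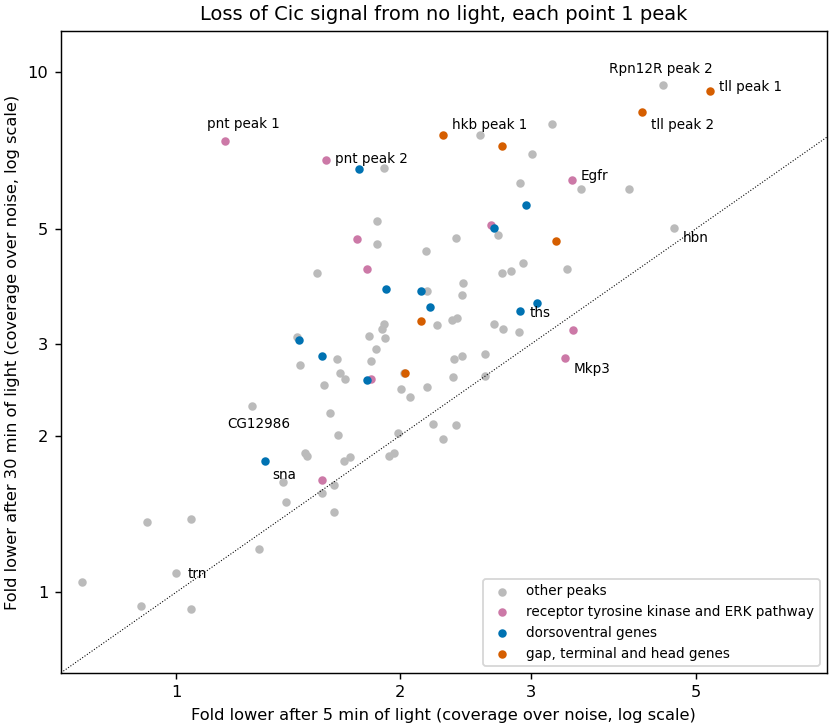
Fold by which coverage over noise was lower than in no light after 5 min (horizontal) and after 30 min of light (vertical), both on log axes, with 1 point per final peak, coloured by gene list (1 colour per gene) and a dotted line of equality, in windows centred anew in each condition. The promoter peak of pnt lies at 1.16 and 7.38, and that of tll at 5.22 and 9.21.

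Constant ERK activity was examined by comparing active Torso with wild type. The peaks had been called on these same wild type libraries, so chance highs in wild type can add to the falls. Cic signal was lower at 99 peaks and higher at 4 by z-score, with a median difference of -4.56 (-5.16 to -4.13). Coverage over noise was 2.20-fold lower at the median peak (2.06 to 2.38) and lower beyond counting error at 90 peaks. As after 5 min of light, the largest fall in z-score was at tll, with 4.20-fold lower coverage at peak 1 (3.57 to 4.97) and 5.29-fold at peak 2 (4.24 to 6.69), and hbn was 5.95-fold lower (4.39 to 8.27). The window of tll peak 1 lay 320 bp from its wild type position, and aligned by shape it was 3.46-fold lower (2.97 to 4.03). The promoter peak of pnt was not lower beyond counting error, with z-scores of 19.1 in wild type and 17.04 with active Torso (1.07-fold lower, 0.926 to 1.23).

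All 7 peaks of gap, terminal and head genes were lower, with a median z difference of -12.9 at percentile 0.725 of matched lists. Their median of 2.44-fold lay at percentile 27.1 of the ratio. Here fkh was 3.03-fold lower (2.48 to 3.73) and hkb peak 1 2.11-fold (1.85 to 2.42). Of the known Cic targets 10 of 11 peaks and of the receptor tyrosine kinase list 10 of 11 peaks were lower beyond counting error, all but pnt peak 1 in both. Examples are Egfr with 2.59-fold (2.096 to 3.21), Mkp3 with 2.36-fold (1.88 to 2.97), ind with 2.17-fold (1.69 to 2.77) and cic peak 1 with 3.14-fold (2.26 to 4.32).

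Dorsoventral genes were lower by a smaller median, 1.77-fold against 2.22-fold in matched lists (percentile 95.8 of the ratio and 80.9 of the z difference), and 10 of 12 peaks were lower beyond counting error. There zen was 3.08-fold lower (2.55 to 3.75), pnr, a GATA factor gene, 3.09-fold (2.25 to 4.24), and dpp peak 1 2.74-fold (2.27 to 3.299). Doc3 was higher, with z-scores of 8.845 with active Torso and 5.87 in wild type, and sna had 10.3 and 12.97. The peaks of betaTub60D (ratio 2.67, 2.05 to 3.47) and CG3168 (ratio 1.53, 1.22 to 1.94), singled out after their values were seen, were the other 2 higher beyond counting error.

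The last comparison set 30 min of light beside constant Torso activity. Signal was lower after 30 min of light at 75 peaks and higher at 28, with a median z difference of -0.784 (-1.49 to -0.519). Coverage over noise was 1.21-fold lower at the median peak, lower beyond counting error at 38 and higher at 8. The difference was largest at pnt peak 1, where the z-score was 2.45 after light and 17.04 with active Torso (4.66-fold lower, 3.60 to 6.06). It was next largest at CG12986 (12.4 and 23.8), srp peak 1 (2.48 and 12.7) at a GATA factor gene, hkb peak 1 (4.34 and 13.8) and Doc2 (6.88 and 15.3).

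Known Cic targets were lower after light at all 11 peaks, 8 of them beyond counting error, with a median of 1.93-fold against 1.37-fold in matched lists (percentile 0.725 of the ratio and 15.0 of the z difference). The receptor tyrosine kinase list had a median of 1.79-fold (percentiles 1.06 and 15.2). These lists share 5 of their 11 peaks, the 3 of pnt and the 2 of aos, so the results are not separate. The dorsoventral peaks were all lower, 6 of 12 beyond counting error, from 3.08-fold at Doc3 (2.31 to 4.18) and 2.88-fold at zen2 (2.09 to 4.04) to 1.01-fold at pnr (0.665 to 1.52). Peaks with more signal after light included prd peak 1, with z-scores of 1.60 after light and 0.386 with active Torso, and CG17300, with 2.39 and 1.23. The groups differ in genetic background as well as in the duration of ERK activity.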

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

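Of the tests in this closing section, only the test of window centring for the signal left after 30 min of light was written before its result was seen, and all others were chosen afterwards.

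Among the calls against the untagged control, 8 with a fold enrichment of at least 5 were missing from the final list, although every final peak lay above 5. They stood out as signal in a table that the comparisons of conditions do not use. The gene rl, which encodes ERK, held 5 of them on chromosome 2R (dm6), at 1072177 to 1072528 with 15.16-fold enrichment, 1076569 to 1076829 with 14.21, 1080236 to 1080513 with 10.18, 1105782 to 1106065 with 8.485, and 1113290 to 1113549 with 13.91. Dsor1, which encodes the ERK kinase MEK, held 2 on X, at 9248495 to 9249190 with 29.22-fold, the highest of all calls, and at 9249339 to 9249927 with 8.911. The last, with 24.79-fold, lay at 3R 9784242 to 9784840 at the metallothionein gene MtnA and CG8500.

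Extra DNA made of the gene bodies of rl, Dsor1 and MtnA alone would give calls inside these genes and none beside them. A construct that also carried sequence next to a gene would give calls past its end as well. Of the calls in or within 5 kb of them, 7 lay wholly inside rl or Dsor1, and 1, the call at MtnA, did not lie wholly inside the gene and reached past its end at 9784370. The call at MtnA goes against DNA of the gene body alone, but not against a construct with sequence next to the gene. The 7 calls inside genes do not single out extra DNA either, because 55 final peaks also lay wholly inside gene bodies. The calls in rl were 260 to 352 bp long in a gene of 54466 bp, so most of its body was not called. Whether calls lay on exons was not examined. For these reasons the test cannot tell the explanations apart. Local binding or copy differences between the tagged and untagged lines remain possible, and the signal matrices do not cover these sites. No biological explanation was tested.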

How the results depend on the processing

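The falls in signal after 5 and 30 min of light and with active Torso kept their direction under every alternative, as did the rise of no light over wild type and the lower signal after 30 min of light than with active Torso. The difference at 1 min did not. By z-score 33 peaks were lower and 70 higher at 1 min, against 48 and 55 with 100 bp on each side, 14 and 89 with scaling to the reference flank, 52 and 51 with the maximum, and 6 and 97 on both log2 scales. For 30 min against active Torso the split was 75 and 28, and 49 and 3 among peaks at or above the median reference signal. Below, differences are median z-scores over peaks unless log2 is named, values of single peaks are those that changed sign, and the cause was not tested unless stated. With 100 bp on each side the difference was 0.132 at 1 min, -8.50 at 5 min, -11.1 at 30 min and -7.83 for active Torso, and 39 peaks fell at every step, against 25. Narrow windows hold the summit, so the larger falls at 5 and 30 min and with active Torso follow from construction, whereas the smaller difference at 1 min does not. At 1 min wntD -3.52, Doc2 -1.53, CG12986 -1.14, srp peak 2 -0.185, milt -0.0868 and salm -0.0838 changed sign there. With 500 bp the differences were -2.89 at 5 min, -3.99 at 30 min, -2.75 for active Torso and -0.386 for 30 min against active Torso, and at 1 min hkb peak 2 -0.343, cic peak 2 -0.0273, tll peak 3 -0.116 and pnt peak 3 -0.237 changed sign. Subtracting the flank changed the sign of Rpn12R peak 1 (-0.961) in no light against wild type and of wntD (-1.30) at 1 min. It did so for srp peak 2 (1.54) and cic peak 2 (0.332) at 5 min, for the same peaks (2.63 and 0.251) at 30 min and with active Torso (1.48 and 0.338), and for srp peak 2 (2.097) in 30 min against active Torso. By wild type positions the flank of each overlaps its neighbour, srp peak 1 or cic peak 1, with summits 771 and 939 bp away. That neighbour is subtracted and falls itself, so these changes of sign need not be rises at the peaks. Scaling to the reference flank gave 2.09 at 1 min, where hkb peak 1 (3.18), tll peak 1 (4.00), pnt peak 1 (2.95) and tll peak 2 (2.77) became higher, and 9 peaks fell at every step. With the maximum in place of the mean the difference was -0.262 at 1 min, reversed, -10.9 at 5 min, -13.4 at 30 min and -9.78 for active Torso, and 44 peaks fell at every step. With it hkb peak 2 (-0.474), ths (-0.161) and abd-A (-0.620) changed sign in no light against wild type, and at 1 min wntD -9.42, Doc2 -3.53, srp peak 1 -0.830, hkb peak 2 -0.421, zfh1 -0.562, CG17300 -1.10, CG15480 -2.21, srp peak 2 -1.18 and salm -0.690 did. On a log2 scale with 1 added the differences were 0.23 for no light against wild type, 0.31 at 1 min, -0.84 at 5 min, -1.30 at 30 min, -0.93 for active Torso and -0.20 for 30 min against active Torso. Their size differs because the unit differs. At 1 min hkb peak 1 (0.19), tll peak 1 (0.24), pnt peak 1 (0.23) and tll peak 2 (0.23) changed sign, and 3 peaks fell at every step. Peaks at or above the median reference signal gave 3.07 for no light against wild type, -9.43 at 5 min, -12.6 at 30 min, -6.82 for active Torso and -2.32 for 30 min against active Torso, since only strong peaks were kept. Within 3000 bp of a start site lay 67 peaks, against 39 within 1000 bp, a wider limit by construction. The stricter thresholds of the peak calls were passed by 360 (-log10 q) and 341 (fold enrichment) of 468, and 6 lists passed with the upper part of the wild type signal, against 4. The added lists were Hox (abd-A) and zygotic activation (sisA), each on 1 gene with an adjusted p of 0.0488 in the one-sided Fisher's exact test.

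Further alternatives were chosen after seeing the data. The log2 ratio without 1 added gave 0.26 for no light against wild type, 0.34 at 1 min, -1.02 at 5 min, -1.63 at 30 min, -1.14 for active Torso and -0.28 for 30 min against active Torso, and hkb peak 1 (0.20), tll peak 1 (0.25), pnt peak 1 (0.24) and tll peak 2 (0.25) changed sign at 1 min. With 1000 bp on each side the differences were 0.604, 0.345, -1.69, -2.33, -1.47 and -0.234 in the same order. There pnt peak 1 (0.804), tll peak 2 (0.175), hkb peak 2 (-0.459), cic peak 2 (-0.222) and tll peak 3 (-0.391) changed sign at 1 min, pnt peak 2 (0.442) at 5 min, and hkb peak 2 (0.280) and pnt peak 2 (1.22) with active Torso. Windows this wide reach into the neighbouring peak at pnt peaks 1 and 2 and at cic, whose wild type summits lie 1055 and 939 bp apart. At hkb (1561 bp) and at tll peaks 2 and 3 they do not reach the called neighbour, and the cause was not tested. Without 14 peaks with overlapping windows all differences kept direction and size. Gene bodies within 10000 bp gave 5 lists. The added list was Hox (2 genes, one-sided Fisher's exact test, adjusted p = 0.0143), and 76 of 1000 random placements on the same chromosomes did as well, against 0 for each of the other 4. Aligning each window to that of its reference by shape gave 1.36, 0.562, -4.83, -6.998, -4.59 and -0.854 in the order above, and no named peak that differed beyond counting error changed sign. Of the windows, 3 lay over 250 bp from their reference at 5 min, 12 at 30 min and 9 with active Torso, but only 84, 50 and 62 matched it with a correlation of at least 0.7, so the place of the others is unsure. No paired analysis was possible because the matrices combine the replicates of a condition and their columns carry no replicate. For the same reason, leaving out each replicate was not run. The motif search with its 3 alternatives, distances to start sites of protein-coding genes only, start sites within 10000 bp and random placements relative to start sites were not run. Depth limits weak peaks, as the median peak had 60.7 read equivalents after 30 min of light.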

Other observations

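Loss of Cic after 5 min of light was uneven over peaks. If a lower yield of the immunoprecipitation had scaled all peaks alike, 1 common factor of the excess over noise would describe them. Beyond counting error 53 peaks lay outside that factor, against 23 for no light and wild type. A simulation with 1 factor and counting error only had 7. Window centring may not account for this, because 54 peaks lay outside with 500 bp on each side. The residual in counting SDs was 9.97 at pnt peak 1, 9.28 at CG12986 and 5.75 at sna, and -11.4 at tll peak 1. The untagged level over its lowest value was 1.08, 2.32, 1.88 and 1.30 at these peaks, so background may hold up the signal of CG12986 and sna. Other peaks with a high untagged level went both ways. The residual was 2.82 at CG15480 (untagged level 3.04), but -2.33 at zen (2.90) and -4.29 at Mkp3 (2.17). Library scatter of the combined 5 min matrix is unknown, so no cause is given.

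Signal left after 30 min of light was weighed against material that the GFP antibody takes down without tagged Cic. The 30 min level at the median peak was 2.70 times the untagged level and all peaks but 1 lay above it, but only the 30 min windows are centred on their own highest point, and the untagged level is that of MACS2 at the wild type summit over its lowest level. After division by a flank centred in the same way the ratio was 1.47 (95% interval over peaks 1.32 to 1.61), above the 1.2 set for such material as the whole signal and below the 1.5 set for excluding it, so this stays open. Ranks of the 30 min signal followed the untagged level (correlation 0.528, 0.465 given no light) and the no light signal (0.448, 0.361 given the untagged level). The centre exceeded a centred flank by a median z-score of 1.30 (1.11 to 1.58), which met the mark set beforehand against centring as the whole signal. That flank was centred over a shorter stretch than the peak windows, so this test cannot settle how much centring adds. No biological explanation was tested.

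Over peaks, active Torso ranked more like 5 min of light (correlation 0.867) than like 30 min of light (0.694). Signal at 30 min was weak, and its ranks also followed no light less closely (0.448) than those of 5 min did (0.767). The difference therefore does not show which duration active Torso resembles. Peaks at most 1000 bp from a start site were 1.91-fold lower after 5 min and 3.28-fold after 30 min, and the 64 others 2.15-fold and 3.10-fold. With active Torso these groups were 2.13-fold and 2.22-fold lower. Among genes seen only after the values were examined, betaTub60D rose from a z-score of 2.71 in wild type to 9.12 with active Torso, and CG3168 from 4.90 to 7.88.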
